A study of Danio rerio with 20 samples.

How the data were processed

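Gene expression was measured in whole zebrafish embryos with 1-colour Agilent arrays, 1 array per RNA sample and 20 arrays in all. The embryos came from 4 groups of 5 independent replicates: 0.1% ethanol as the vehicle, or 10 µM of cyclopamine, SANT-2 or GANT-61, each from 0.5 to 24 h after fertilization. Per the labels, total RNA was extracted with Trizol, amplified and labelled with Cy3. The scanner files hold the Cy3 intensity of each spot, background-subtracted and spatially detrended by Agilent Feature Extraction 10.1.1.1 per the file headers, and not normalized between arrays. The authors also deposited a table of normalized log2 values, whose sorted values nearly coincide between arrays. That table was used as an alternative only.

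The intensities were taken to log2, spots that the scanner software had marked as outliers were set aside, and the 75th percentile of the non-control spots of each array was subtracted. Spots of the same probe were averaged. Each array carried 14694 non-control probes. Accessions and names were looked up in the reference gene table, assembly GRCz12tu, used for names alone: 9185 probes matched 1 gene symbol and 5509 matched none, 3750 of these being named by an Ensembl transcript only. For the 37 genes with more than 1 probe, the brightest was kept, which left 14657 genes. A gene was tested if its probe was well above background on at least 4 of the 5 arrays of at least 1 group. This left 11433 genes, 7859 of them with a symbol, and set 3224 aside as too dim.

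The 6 pairs of groups were compared with limma 3.58.1 in R 4.3.3, in 1 model with a mean per group, and p-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison. A gene was called at an adjusted p under 0.05. Standard errors and 95% intervals come from the same model. Where all arrays of a group lay under the background limit, the fold is given as a lower bound. Beside each count stand values with slide as a block, and how many called genes changed in the same direction on each of the 4 slides. Slide, or the replicate number in the titles, entered the model as a term. The deviations of each gene from its group mean were correlated between arrays of the same number, and the lowest of the 5 correlations was 0.46 for cyclopamine and ethanol, 0.25 for cyclopamine and SANT-2, 0.21 for cyclopamine and GANT-61 and 0.14 for SANT-2 and GANT-61. It was -0.01 for SANT-2 and ethanol and -0.05 for GANT-61 and ethanol, each between arrays on different slides. Between arrays of different groups the median correlation was 0.56 on the same slide and -0.16 on other slides. The values of 0.25, 0.21 and 0.14 also came from arrays on different slides. They and those of -0.01 and -0.05 lay above the median of -0.16, so the number may add to a shared slide. The spread of the correlations on other slides was not examined, so the check does not settle whether the numbers mark pairs. Arrays of the same number lay on 1 slide in 3 to 5 of the 5 pairs.

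A total of 28 gene lists of pathways, tissues and cell types was tested per compound with camera at a preset correlation of 0.01, and again with an estimated correlation. The camera p-values were adjusted over the 84 tests. fry was run beside it. Its directional test asks whether the genes of a list move one way on balance, its mixed test whether they change either way, and neither compares the list with other genes. The mean of the 23 measured hedgehog-responsive genes was taken per array and compared with an exact two-sided permutation test over 252 arrangements, adjusted over the 6 pairs of groups. The overlap of called genes was set beside the number expected by chance. The Pearson correlation of log2 changes across genes was set beside 100 simulated draws of unchanged groups that shared the ethanol arrays. Arrays were shuffled across slides in these draws, and within slides in a further 100. The correlation was also taken with the ethanol arrays split so that the compounds shared none.

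The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, per compound against ethanol, the 10 largest rises and 10 largest falls among called genes that have a symbol, were not named as clones and had all 5 treated arrays on the same side of the ethanol mean. If no gene passed, it took the 5 with the smallest unadjusted p. It took the 5 largest differences each way per pair of compounds, every measured hedgehog gene of the pathway and the responsive list, and from each other list up to 4 members with the smallest adjusted p or, where none passed, the 2 with the highest signal. Genes chosen after their values were seen are named as such.

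The steps were tested on simulated data for cyclopamine against ethanol, with 11433 genes of which 50 were changed at each size. The model without a block recovered 24% of the genes changed by 0.5 on the log2 scale, 66% at 1, 88% at 1.5 and 92% at 2, with 0 false calls. With slide as a block it recovered 46%, 78%, 100% and 98%, with 13 false calls. The alternatives tried were quantile and median scaling, the authors' table, filters on dim probes, slide and replicate blocks, a trended robust spread, array weights, a fit of the groups compared alone, other ways to join probes to genes, stricter thresholds and leaving out each array in turn. Chosen after the data were seen were a normexp background correction on the median spot signals, since the files hold no mean spot signal, the fit without slide 2, quantile scaling with slide as a block, and slide-blocked forms of the list mean, overlap and correlation. Probes without a symbol were tested but are not named here.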

Results

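Messenger RNA levels were measured in whole zebrafish embryos at 24 h after fertilization, after exposure from 0.5 h to 10 µM of cyclopamine, SANT-2 or GANT-61, or to 0.1% ethanol, the vehicle. Cyclopamine, a plant alkaloid, and SANT-2, a synthetic compound, block smoothened, the membrane protein that turns on the hedgehog pathway, and GANT-61 blocks the gli transcription factors at its end. Each group had 5 arrays from independent replicates of 100 embryos. Between 10038 and 12610 probes per array were well above background, with a mean of 11627 ± 785 (SD, n = 5) for ethanol, 11266 ± 863 for cyclopamine, 11472 ± 1021 for SANT-2 and 11521 ± 532 for GANT-61. The arrays lay on 4 slides, each with all 4 groups, and the 75th percentile of the signal was 566 to 763 on slide 2 and 1126 to 2059.5 on the others. The first principal component held 40.9% of the variance, and slide took 90.2% of it and group 6.46%. The number of arrays limits the precision of each value.

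Cyclopamine was compared with ethanol to ask which genes the model inhibitor of hedgehog signalling changes in the embryo. Genes that the pathway turns on in the ventral neural tube and the somites were among the largest falls, together with genes of slow muscle fibres and the small heat shock protein gene hspb9l. The transcription factor gene nkx2.2a, which marks the most ventral neural progenitors, fell 15-fold, a log2 change of -3.92 ± 0.20 (SE, n = 5 per group; adjusted p = 7.01e-10). olig2, needed for motor neurons and oligodendrocytes, fell 7.09-fold (-2.83 ± 0.19; adjusted p = 2.19e-08), and nkx2.9, which acts beside nkx2.2a, fell at least 6.81-fold, its signal being well above background on 0 of the 5 cyclopamine arrays. The slow myosin heavy chain gene smyhc1 fell 8.10-fold (-3.02 ± 0.55; adjusted p = 0.00559), with changes of -4.00 to -1.03 within single slides. In a fit of the compared groups alone smyhc1 did not pass against ethanol or SANT-2.

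Of the 23 measured hedgehog-responsive genes, 11 fell and 0 rose, and 15 were lower when adjusted over the list alone. The mean change of the list was -1.26 and its median -0.54 (camera adjusted p = 1.47e-42, and adjusted p = 3.35e-05 with an estimated correlation). Besides nkx2.2a, nkx2.9 and olig2, the list's called genes in the neural tube were nkx6.1, a gene of motor neuron progenitors, at -1.58 ± 0.16, the floor plate gene foxa at -1.50 ± 0.17 and nkx2.4a at -0.71 ± 0.14. In the mesoderm, nkx3-2, a gene of sclerotome and jaw cartilage, fell by 2.71 on the log2 scale, and the mesenchyme genes foxf1, foxf2a and foxl1 changed by -2.17, -2.18 and -2.30. en1a, which marks muscle pioneer cells, changed by -2.30 ± 0.32. On the cyclopamine arrays foxl1 was well above background on 2 of 5, and en1a, foxf1 and foxf2a on 3 of 5. The call of nkx2.4a was lost with the background correction on median signals (-0.50). That of foxf2a was lost without slide 2 and without ethanol 1, ethanol 3, cyclopamine 2, cyclopamine 3 or cyclopamine 4. The other 12 members did not pass. Among them were foxa2 at -0.50, foxa1 at -0.54 and nkx2.4b at -0.50 (adjusted p = 0.597, 0.143 and 0.130), which passed with slide as a block (adjusted p = 0.0141, 0.0379 and 0.00743) and with the replicate number as a block (adjusted p = 0.0292, 0.00156 and 0.00524), as did en1b at -0.47 with the latter alone (adjusted p = 0.0329, against 0.311). nkx2.1 at -0.47, the hedgehog-binding protein gene hhip at -0.45, vax1 at -0.22, vax2 at -0.19, en2a at 0.04, en2b at 0.25, pax2a at 0.04 and sim1a at 0.30 passed in none of these fits.

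The genes that encode the pathway itself did not pass: 0 of 16 measured components changed (camera adjusted p = 0.572). The ligand gene shha differed by -0.10, smo by -0.12, gli2a by 0.14, gli2b by 0.29, gli3 by 0.39 ± 0.15 and scube2, whose product releases the ligand, by 0.36. Genes not matched to a probe included the responsive genes nkx2.2b, nkx6.2 and prdm1a, and gli1 and dhh were too dim to test.

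Slow muscle was the other list that held with an estimated correlation. Of its 7 measured genes 4 fell, and 5 when adjusted over the list alone, with a mean change of -1.66 and a median of -2.33 (camera adjusted p = 2.62e-16, and adjusted p = 4.26e-05 with an estimated correlation). The mean was lower on each slide, from -1.98 to -1.10. fry's test for a move in one direction passed for this list and the hedgehog-responsive one alone (adjusted p = 1.72e-07 and 2.45e-08). The myosin light chain genes myl13 and myl10 fell 7.93-fold and 6.86-fold and the troponin C gene tnnc1b 5.04-fold. Outside this list, the largest falls included hspb9l, 22.0-fold lower (-4.46 ± 0.26, adjusted p = 4.82e-09), the LIM domain gene fhl1a, 8.91-fold lower, the troponin I gene tnni4b.2, 7.24-fold lower and well above background on 4 of 5 cyclopamine arrays, and the actin gene actc2, 6.59-fold lower. Of the 27 fast and general muscle genes 2 fell, the myogenic regulator myod1 (-0.79 ± 0.15) and the acetylcholine receptor gene chrna1 (-0.70 ± 0.14). The chrna1 call was lost without ethanol 4 or cyclopamine 2. That list was lower by camera (mean -0.22, adjusted p = 0.000937, but adjusted p = 0.943 with an estimated correlation), and its mean was -0.08, -0.50, 0.01 and -0.45 on the 4 slides. With slide in the model the interval of that mean, -0.85 to 0.41, includes 0, and without cyclopamine 2 the mean turned to 0.023. The muscle myosin chaperone genes unc45b (-0.49) and hsp90aa1.1 (-0.50) did not pass, unless with slide as a block (unc45b, adjusted p = 0.00552) or the replicate number as a block (adjusted p = 0.0193 and 0.0476).

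In the ventral midline, floor plate and notochord list 1 of 15 genes fell, foxa, which the hedgehog-responsive list also holds, and 2 when adjusted over the list alone (mean -0.33, median -0.31; camera adjusted p = 4.31e-06, and adjusted p = 0.173 with an estimated correlation), with slide means of -0.54 to -0.14. With slide in the model the interval of the list's mean, -0.50 to -0.15, excludes 0. The exact permutation p without slide was 0.0238, not adjusted over the lists. The list's notochord gene ccn2a differed by -0.50 (adjusted p = 0.269), and passed with slide as a block (adjusted p = 0.0131) and with the replicate number as a block (adjusted p = 0.0165). In the heart list 0 of 9 genes passed and 5 were lower when adjusted over the list alone (mean -0.41; camera adjusted p = 0.00141, and adjusted p = 0.173 with an estimated correlation), with slide means of -0.53 to -0.25; mef2ca differed by -0.13 and gata5 by 0.05. The heart genes nkx2.5 (-0.56), the myosin light chain gene myl4 (-1.72) and the troponin gene tnnc1a (-0.51), named after their values were seen, passed with slide as a block (adjusted p = 0.0306, 0.0226 and 0.0108).

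Single genes of other tissues also fell. Among neurons 1 of 23 did, phox2a, a regulator of noradrenergic and cranial motor neurons (-1.23 ± 0.23, 2.35-fold). In the eye field list 2 of 14 genes fell, six6a (-1.56 ± 0.16, 2.96-fold; above background on 4 of 5 cyclopamine arrays) and foxd1, a gene of the temporal retina (-1.06 ± 0.20). When adjusted over the list alone 2 members were higher and 2 lower. The list's mean was -0.09 and its median 0.08 (camera adjusted p = 0.989), and fry's test for change in either direction gave an adjusted p of 5.47e-08. The arterial Notch ligand gene dll4 fell by 0.82 on the log2 scale, 1 of 12 vascular genes, and the pancreas gene pdx1 by 0.72, 1 of 12 endoderm genes and 1 of 2 lower when adjusted over the list alone. The pdx1 call was lost without slide 2, with the background correction on median signals (-0.48) and in a fit of cyclopamine and ethanol alone, where foxd1, foxf2a, chrna1, dmrt3a and dap1b did not pass either. The named genes that rose were the Notch-related repressor her3 (0.89 ± 0.13, 1.85-fold; adjusted p = 0.000639), the neural transcription factor gene dmrt3a (0.76 ± 0.15) and dap1b (0.53 ± 0.12). The dap1b call was lost with every other scaling, with no filter and without any array but ethanol 3, and that of dmrt3a without ethanol 2. The dorsal neural tube list had 0 of 13 genes called and 2 higher when adjusted over the list alone (camera adjusted p = 0.101); msx1b differed by 0.28 and pax6b by 0.57, the latter passing with slide as a block (adjusted p = 0.00151) and with the replicate number as a block (adjusted p = 0.0114). The motor neuron gene mnx1 (-0.54), the eye gene mab21l2 (0.57) and prox1a (-0.33) passed with slide as a block (adjusted p = 0.0425, 0.0156 and 0.0306), and mnx1 with the replicate number as a block too (adjusted p = 0.0151).

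The lists for other tissues did not pass the list test under cyclopamine, and 0 of their members passed: lens crystallins (camera adjusted p = 0.373), neural crest (0.519), erythroid (0.773) and myeloid cells (0.997), epidermis (0.183), hatching gland (0.846), presomitic mesoderm (0.806, with 1 gene higher and 1 lower when adjusted over the list alone), extracellular matrix (0.997) and germ cells (0.519). This does not show that they stayed level. With slide in the model the interval of the mean was -0.27 to 0.83 for lens crystallins and -0.05 to 0.28 for germ cells. The members of these lists were tested without a block. With slide as a block some passed, such as crygmx of the lens list and pts of the neural crest list, both higher (adjusted p = 0.0126 and 0.0352). They are named after their values were seen. The vascular and endoderm lists had a camera adjusted p of 0.459 and 0.476, and the neuron list 0.101. The stress and metabolism lists also held 0 called genes in the fit without a block. Their camera adjusted p was 0.516 for aryl hydrocarbon receptor targets, 0.476 for oxidative stress, 0.699 for heat shock and 0.815 for p53 targets. It was 0.373 for cholesterol synthesis, 0.373 for lysosome, 0.491 for cell cycle and 0.704 for feedback targets of other signalling pathways.

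Across all 11433 genes, limma called 100 under cyclopamine, 4 higher and 96 lower, and 48 of them differed at least 2-fold; 616 passed without adjustment, where 572 were expected by chance. All 100 changed in the same direction on each of the 4 slides, as did 29.9% of all genes tested. With slide as a block 250 passed, 57 higher and 193 lower, the 100 among them, and with the replicate number as a block 259, 44 higher and 215 lower. Array weights gave 201 and a fit of cyclopamine and ethanol alone 53.

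SANT-2 was compared with ethanol to ask whether another smoothened blocker at the same concentration changes the same genes. No gene was called by limma, and 130 passed without adjustment, where 572 were expected; with array weights 3 were called, all higher. Genes that fell under cyclopamine lay near the ethanol level: olig2 differed by -0.07 (95% interval -0.47 to 0.32), nkx2.9 by -0.08 (-0.91 to 0.75), nkx6.1 by 0.12 (-0.22 to 0.45), foxf1 by -0.01 (-0.35 to 0.32) and the slow muscle gene myl10 by 0.12 (-0.45 to 0.69). For nkx2.2a the interval ran from -0.42 to 0.41, which excludes a fall of the size seen under cyclopamine.

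Of the 23 hedgehog-responsive genes 0 passed under SANT-2 (camera adjusted p = 0.806), and so did 0 of 16 pathway components (camera adjusted p = 0.519) and 0 of 7 slow muscle genes (camera adjusted p = 0.997). en1a differed by -0.18 (-0.85 to 0.49), foxl1 by 0.10 (-0.26 to 0.47), myl13 by 0.05 (-0.64 to 0.74), nkx2.4a by -0.15, sim1a by 0.59, hhip by 0.20, gli3 by 0.24, shha by -0.14 and smo by -0.07. The list with the lowest camera adjusted p was the ventral midline, floor plate and notochord list, at 0.0523, and it passed with slide as a block (adjusted p = 0.0108) but not with an estimated correlation (adjusted p = 0.866). Its mean differed by -0.09 with slide in the model (interval -0.27 to 0.09), and its notochord gene ccn2a by -0.06. No other list passed in these fits. The 2 genes with a symbol among the 5 with the smallest unadjusted p were tlcd5b (1.02 ± 0.30) and lingo3a (1.05 ± 0.31), and neither passed. With slide as a block limma called 0 genes and 403 passed without adjustment, the smallest adjusted p being 0.892.

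GANT-61 was compared with ethanol to ask what a blocker of the gli factors, the last step of the pathway, changes at the same concentration. It raised a set of genes whose number varied with the fit, 18 genes being called in all, and the hedgehog-responsive genes lay near the ethanol level. pm20d1.1, which encodes a secreted peptidase, rose 4.2-fold (2.07 ± 0.26 SE, n = 5 per group; adjusted p = 0.000373), elavl2, an RNA-binding protein gene of neurons and germ cells, rose 3.36-fold (1.75 ± 0.27; adjusted p = 0.00357) and lim2.2, a lens fibre membrane protein gene, rose 3.31-fold (1.73 ± 0.22; adjusted p = 0.000373). Within slides these changes ran from 0.97 to 2.27, from 0.41 to 2.25 and from 0.82 to 2.07.

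The other named genes that rose were the pancreatic amylase gene amy2al1 (2.46-fold, 1.3 ± 0.25; adjusted p = 0.0381), the signalling adaptor skap1 (1.07 ± 0.21), the patterning gene irx3b (1.99-fold, 0.99 ± 0.15; adjusted p = 0.00274) and birc5b, a gene of cell division and survival (1.84-fold, 0.88 ± 0.17). The only named gene that fell was the membrane protein gene emp3b, 1.98-fold (-0.98 ± 0.18; adjusted p = 0.0237), well above background on 2 of 5 GANT-61 arrays. The calls of amy2al1, skap1 and birc5b were lost with quantile, median and the authors' scaling, with no filter, with a trended robust spread and without most single arrays. With the background correction on median signals their changes shrank to 0.52, 0.49 and 0.35. emp3b lost its call with that correction (-0.35), with the trended robust spread and without 6 of the 10 arrays in turn. In a fit of GANT-61 and ethanol alone pm20d1.1, elavl2, irx3b and these 4 genes did not pass. Of the hedgehog-responsive genes 0 of 23 passed (camera adjusted p = 0.990): nkx2.2a differed by 0.06 (95% interval -0.36 to 0.48), olig2 by -0.05 (-0.45 to 0.34), nkx2.9 by 0.01 (-0.82 to 0.85), nkx6.1 by 0.12 (-0.22 to 0.46), foxa by 0.19 (-0.18 to 0.56) and en1a by -0.55 (-1.21 to 0.12). Of the 16 pathway components 0 passed (camera adjusted p = 0.822), with gli3 at 0.37, shha at 0.02 and smo at 0.03. Among slow muscle genes 0 of 7 passed (camera adjusted p = 0.245), with myl10 at 0.02 (-0.55 to 0.59) and myl13 at -0.16.

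**Figure D1:**
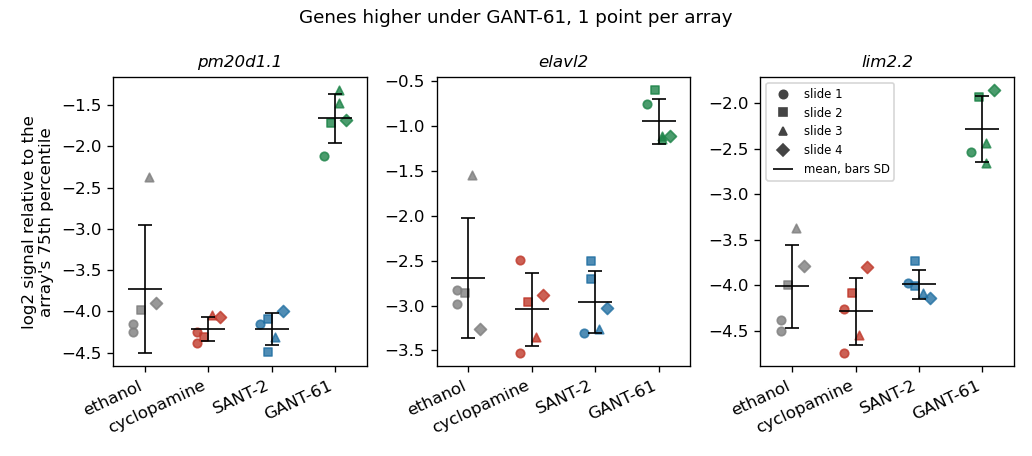
Log2 signal relative to the 75th percentile of each array for pm20d1.1, elavl2 and lim2.2 in each of the 5 arrays per group (marker shape for slide, bar for mean ± SD). In GANT-61 embryos pm20d1.1 was 4.2-fold above ethanol, and ethanol array 4 lay above the other ethanol arrays in pm20d1.1 and elavl2.

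A pair of lists shifted under GANT-61, neither with an estimated correlation. Germ cell and maternal transcripts were higher (mean 0.43, median 0.44; camera adjusted p = 0.00253, and adjusted p = 0.304 with an estimated correlation), with 0 of 14 members called, 1 higher when adjusted over the list alone, and means of 0.33 to 0.60 on the 4 slides. With slide in the model the interval of the list's mean, 0.26 to 0.60, excludes 0. The exact permutation p without slide was 0.00794, not adjusted over the lists. The egg coat genes zp3 and zp2.1 differed by 0.45 and 0.44. Of this list, the pluripotency gene nanog (0.95, adjusted p = 0.000544) and the germline gene piwil1 (0.89, adjusted p = 0.0222), named after their values were seen, passed with slide as a block. Fast and general muscle was lower (mean -0.24; camera adjusted p = 0.0132, and adjusted p = 0.943 with an estimated correlation), with 0 of 27 members called; mylpfa differed by -0.12 and desma by 0.07, and the slide means were 0.12, -1.30, -0.35 and -0.19. With slide in the model the interval of this mean, -1.05 to 0.23, includes 0, and without slide 2 the mean turned to 0.023. With slide as a block erythroid cells passed as lower (adjusted p = 0.0111, against 0.0606 without and adjusted p = 0.943 with an estimated correlation), though the interval of their mean, -0.48 to 0.11, includes 0. The chaperone gene hspa8 (0.47) also passed with slide as a block (adjusted p = 0.0477). Lens crystallins and vascular genes each had 1 member higher when adjusted over the list alone (camera adjusted p = 0.245 and 0.457), and heart genes had a camera adjusted p of 0.112. Without a block no list held a called gene. With slide as a block members of other lists passed too, such as crygmx of the lens list and pts of the neural crest list (adjusted p = 0.0474 and 0.0467), named after their values were seen.

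Limma called 18 genes under GANT-61, 17 higher and 1 lower, and 14 of them differed at least 2-fold; 10 of the higher genes have a symbol, and 718 genes passed without adjustment. All 18 changed in the same direction on each slide, as did 21.9% of all genes tested. With slide as a block 206 genes passed, 185 higher and 21 lower, the 18 among them. With quantile normalization as well, 88 were higher and 26 lower. The share higher depended on scaling: 11 rose and 1 fell with median centring, 14 and 3 with quantile normalization, 15 and 3 in the authors' table. The count was 31 without ethanol 4, 11 without ethanol 2, 101 without slide 2, 5 in a fit of GANT-61 and ethanol alone and 1347 with array weights, 1137 higher and 210 lower.

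The compounds were then compared with each other at the same concentration, to ask whether they differ in the hedgehog response itself. The mean of the 23 hedgehog-responsive genes per array was -1.92 ± 0.13 (SD, n = 5) for ethanol, -3.19 ± 0.26 for cyclopamine, -1.88 ± 0.10 for SANT-2 and -1.86 ± 0.13 for GANT-61, on the log2 scale relative to the 75th percentile. Each cyclopamine array, from -3.38 to -2.75, lay under each of the other 15, from -2.13 to -1.76. Cyclopamine differed from ethanol by -1.26, from SANT-2 by -1.31 and from GANT-61 by -1.33, each with an exact permutation p of 0.00794, the smallest that 252 arrangements can give (adjusted p = 0.0159). On the 4 slides the difference from SANT-2 was -1.61 to -0.91 and that from GANT-61 -1.55 to -0.93. With arrangements kept within slides the exact p was 0.0417 against ethanol and 0.0278 against the other compounds, the smallest these allow (adjusted p = 0.0833).

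The mean for SANT-2 differed from ethanol by 0.04 (exact permutation p = 0.571; with slide in the model the interval is -0.21 to 0.21) and that for GANT-61 by 0.07 (exact permutation p = 0.413; -0.14 to 0.28). SANT-2 and GANT-61 differed by -0.02 (exact permutation p = 0.786; -0.28 to 0.14).

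**Figure D2:**
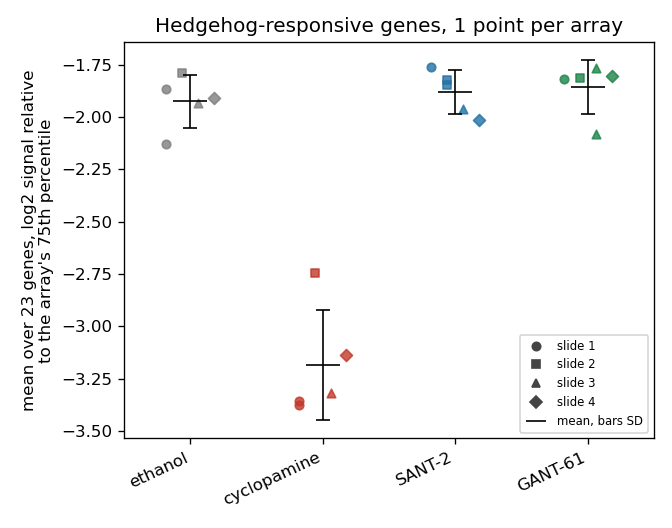
Mean log2 signal of the 23 hedgehog-responsive genes relative to the 75th percentile, for each of the 5 arrays per group (marker shape for slide, black bar for mean ± SD). The cyclopamine arrays lie between -3.38 and -2.75 and all other arrays between -2.13 and -1.76.

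Gene by gene, cyclopamine embryos had less nkx2.2a than SANT-2 embryos, 15-fold (-3.92, adjusted p = 7.17e-10), and than GANT-61 embryos, 15.8-fold (-3.98). nkx2.9 was at least 6.44-fold and at least 6.87-fold lower, hspb9l 22.7-fold and 16.9-fold and smyhc1 8.72-fold and 10.4-fold. Against SANT-2, tnni4b.2 was 8.58-fold lower and her3 1.68-fold higher, the latter not in a fit of these groups alone, and 10 hedgehog-responsive genes differed, olig2 by -2.75, nkx3-2 by -2.76, foxl1 by -2.40, nkx6.1 by -1.70 and foxa by -1.50 among them. Among the 10, foxf2a lost its call with quantile normalization, the authors' table, the background correction on median signals, no filter, array weights, the compared groups alone, without slide 2 and without 8 of the 10 arrays in turn. nkx2.4a at -0.56 and nkx2.4b at -0.54 did not pass (adjusted p = 0.103 for both) unless with slide as a block (adjusted p = 0.0410 and 0.00660) or the replicate number as a block (adjusted p = 0.0338 and 0.00291). foxa2 at -0.51 did so too, with slide as a block (adjusted p = 0.0410) and the replicate number as a block (adjusted p = 0.0267), and foxa1 at -0.50 with the latter (adjusted p = 0.00276).

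Against GANT-61, 12 hedgehog-responsive genes differed, with olig2 at -2.77, nkx3-2 at -2.89, foxa at -1.69 and nkx2.4b at -0.61, and fhl1a was 8.93-fold lower. Higher in cyclopamine than in GANT-61 embryos were emp3b (1.48), the cell junction gene lin7b (0.96), her3 (0.85), dmrt3a (0.84) and tprg1 (0.76). In a fit of these groups alone dmrt3a did not pass. Of the 12, en1a and foxf2a lost their call in that fit. nkx2.4a and foxf2a lost it with quantile normalization, the authors' table and the background correction on median signals, nkx2.4a also with median centring, and foxf2a also without slide 2 and without 6 of the 10 arrays in turn. The nkx2.4b call was lost with median centring, the background correction, the compared groups alone, without slide 2 and without cyclopamine 4, GANT-61 2 or GANT-61 5. That of lin7b was lost with no filter, the compared groups alone, without slide 2 and without 6 of the 10 arrays in turn. foxa1 (-0.55), foxa2 (-0.51), nkx2.1 (-0.65) and hhip (-0.85) passed with slide as a block (adjusted p = 0.0356, 0.00342, 0.0148 and 0.0476) and with the replicate number as a block (adjusted p = 0.000838, 0.0144, 0.0199 and 0.0382), and the ligand gene shhb (-0.32) with slide alone (adjusted p = 0.0247).

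Between SANT-2 and GANT-61, 0 of the 23 hedgehog-responsive genes passed; nkx2.2a differed by -0.07 (95% interval -0.49 to 0.35) and olig2 by -0.02 (-0.42 to 0.38). Of the genes that GANT-61 raised, SANT-2 embryos had 5.86-fold less pm20d1.1 (-2.55, adjusted p = 5.54e-05), 4.04-fold less elavl2 and 3.26-fold less lim2.2. They also had 5.76-fold less sycp3, a meiotic chromosome gene, and less spdya, a regulator of oocyte maturation (-1.54), which did not pass against ethanol without a block. In SANT-2 embryos emp3b was 2.46-fold higher and lin7b 2.19-fold. The spdya call was lost in the authors' table. The emp3b difference shrank to 0.35 and lost its call with the background correction on median signals. The lin7b call was lost with no filter, the compared groups alone, without slide 2 and without 9 of the 10 arrays in turn.

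Limma called 86 genes between cyclopamine and SANT-2, 2 higher and 84 lower, 45 of them at least 2-fold (421 without adjustment; 179 with slide as a block and 204 with the replicate number as a block). Between cyclopamine and GANT-61 it called 208, 24 higher and 184 lower, 83 at least 2-fold (1024 without adjustment; 610 and 644 with these blocks), and between SANT-2 and GANT-61 30, 3 higher and 27 lower, 24 at least 2-fold (428 without adjustment; 114 and 120 with these blocks). A fit of the compared groups alone gave 35 between cyclopamine and SANT-2 and 120 between cyclopamine and GANT-61. The latter count was 441 with array weights and 318 without slide 2, and that between SANT-2 and GANT-61 was 56 with array weights. On each of the 4 slides all 86, 206 of the 208 and all 30 kept their direction. Of all genes tested, 17.2%, 21.7% and 21.7% did so in these comparisons.

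No gene called under cyclopamine was called in the same direction under GANT-61, where 0.00595 higher and 0.0084 lower were expected by chance, so the 0 says little, and SANT-2 had no calls to share. With slide as a block 11 genes rose under both cyclopamine and GANT-61, where 0.922 were expected, and none fell under both. Of these, the lens gene crygmx (0.80 and 0.68), the autophagy gene map1lc3c (0.34 and 0.60), the ribosomal protein gene rpl13a (0.29 and 0.36), pts (0.57 and 0.57) and fam169aa (0.35 and 0.36) have a symbol and are named after their values were seen. Both compounds were compared with the same 5 ethanol arrays. In 100 simulated draws of unchanged groups sharing these arrays, shuffled within slides with slide as a block, 0 genes were shared in every draw. The draws hold no real change, so they do not show how far shared arrays add to real rises. Across genes, which are not independent replicates, the log2 changes of cyclopamine and SANT-2 correlated with r = 0.50, of cyclopamine and GANT-61 with r = 0.39 and of SANT-2 and GANT-61 with r = 0.62. Simulated unchanged groups that shared the ethanol arrays gave means of 0.46, 0.47 and 0.43, with draws of -0.26 to 0.87, -0.38 to 0.91 and -0.45 to 0.89. These draws shuffled arrays across slides, so they also hold slide differences. Shuffled within slides, the means were 0.39, 0.47 and 0.51. With the ethanol arrays split so that the compounds shared none, the mean correlations were -0.04, -0.05 and 0.03. Single splits ranged from -0.47 to 0.32, -0.39 to 0.18 and -0.37 to 0.42. The parts of a split differ in their slides, so slide differences enter these values. They do not decide whether the compounds share a response. The observed correlations of cyclopamine with SANT-2 and with GANT-61 rested on single arrays. Without cyclopamine 3 they were 0.148 and 0.141, and without ethanol 3 they were 0.718 and 0.612.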

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

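The tests of slide differences and of slower development below, and the matching of probes by signal, were chosen after the results were seen.

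Cyclopamine differed from SANT-2 by -1.31 and from GANT-61 by -1.33 in the mean of the hedgehog-responsive genes, each tested directly with an exact permutation test (p = 0.00794). Of 54 groups of 5 arrays checked, 6 held an array farther from the others than Dixon's limit of 0.71 for the gap over the range, and chance gives about 1 in 20. In the hedgehog-responsive mean of GANT-61 embryos, GANT-61 4 lay at -2.08 and the others at -1.82 to -1.76 (ratio 0.834). In nkx2.2a, cyclopamine 3 lay at -3.59 against -4.88 to -4.59 (ratio 0.774) and ethanol 3 at -0.36 against -0.71 to -0.66 (ratio 0.862). Ethanol 4 lay above the other ethanol arrays in pm20d1.1, at -2.37 against -4.25 to -3.90 (ratio 0.813), in elavl2, at -1.54 against -3.26 to -2.83 (ratio 0.750), and in skap1, at -3.07 against -4.41 to -4.16 (ratio 0.812).

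SANT-2 changed no gene by limma, where 130 passed without adjustment, and 3 genes passed with array weights. A response as large as that of cyclopamine, hidden by noise between arrays, is argued against. For 96 of the 96 genes that cyclopamine lowered, the 95% interval under SANT-2 excludes the cyclopamine change. The 96 were picked on these arrays, so their cyclopamine changes may be overstated and are taken without error. The direct comparison, which carries the error of both groups, called 84 genes lower under cyclopamine than under SANT-2. Slide differences counted as noise may account for part of the low count, since 403 genes passed without adjustment with slide as a block, though 0 were called. A weak shift of the genes that cyclopamine lowers stays open: over 184 genes lower under cyclopamine than under GANT-61 the SANT-2 mean differed from ethanol by -0.058 (interval -0.21 to 0.09), against -0.90 for cyclopamine. With a real count of 0, all 100 of 100 splits of the arrays must give as many genes (the highest other gave 1), so the splits decide nothing here.

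GANT-61 raised 17 of its 18 called genes. Slide differences are argued against by the size of the rises with slide as a block, at least 0.77 with a median of 1.61. The genes were picked on these same arrays, so these sizes may be overstated. With the block 17 of the 17 were called, but it lowers the SE and they were called before, so this adds little. All 17 were also higher on all 4 slides, where 21.9% of all genes kept their direction. Genes called on these same arrays tend to agree between slides, so that agreement adds little. A general rise of dim probes is argued against by the 50 uncalled genes nearest each raised gene in signal, whose medians were -0.04 to 0.15 where the smallest rise was 0.77; the median of 0.042 over all 10315 uncalled genes in the raised genes' range decides nothing, since that range holds nearly every gene. Slower development could not be told apart from an effect on these genes, because the mean of 8 lens crystallins, which rise late, differed by 0.17 with an interval of -0.39 to 0.72. Among lists not used for this test, germ cell and maternal transcripts differed by 0.43 (interval 0.26 to 0.60). Intervals included 0 for presomitic mesoderm (0.20, -0.01 to 0.41), fast and general muscle (-0.41, -1.05 to 0.23) and erythroid cells (-0.18, -0.48 to 0.11). Whether these differences reflect stage was not tested. Of 100 splits 1, the real one with 18 genes, gave as many, and the highest other gave 1. Splits can differ from the real groups in their spread over the slides, so this share alone does not exclude chance. Whether the rise is biological is a hypothesis.

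For cyclopamine and ethanol 3 of 100 splits gave as many genes as the real 100, the highest 431. For cyclopamine and SANT-2 2 of 100 splits gave as many as the real 86, the highest 1174. Splits can be uneven over the slides where the real groups are nearly even, so these shares do not exclude chance. The split with 431 set 4 arrays of slide 1 and 1 of slide 4 against 2 of slide 2, 2 of slide 3 and 1 of slide 4. The split with 1174 set 1 array of slide 1, 2 of slide 3 and 2 of slide 4 against 2 of slide 1 and 3 of slide 2. They follow the slides, a structure of the samples that the groups do not share, and with slide as a block the real counts were 250 and 179. For cyclopamine and GANT-61 only the real split, 1 of 100, gave as many as its 208 genes, and for SANT-2 and GANT-61 only the real split, 1 of 100, gave as many as its 30; the highest other was 1 for each. Among splits that part all 5 same-number pairs, as the real one does, the others gave at most 0 genes: 12 splits for cyclopamine and ethanol, 11 for cyclopamine and SANT-2, 9 for cyclopamine and GANT-61 and 11 for SANT-2 and GANT-61. So few splits cannot give a share under 0.05, so they do not exclude chance either.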

How the results depend on the processing

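The background correction on median spot signals, the fits without slide 2, quantile scaling with slide as a block and the within-slide forms of the list mean and the overlap were chosen after the data were seen. Of 2082 values of 78 called named genes, 1890 stayed called in the same direction and 192 lost the call, and of 9562 values of 356 that were not called, 91 gained one in the same direction; none reversed. For lists, 169 of 189 values of the 7 called kept the call, 18 lost it and 2 reversed, and 46 of 2076 values of the other 77 gained a call. The reversed list was fast and general muscle, at 0.023 under GANT-61 without slide 2 and at 0.023 under cyclopamine without cyclopamine 2, where leaving out each array gave -0.40 to 0.023. With slide as a block the counts were 250 for cyclopamine, 206 for GANT-61, 179 for cyclopamine against SANT-2, 610 for cyclopamine against GANT-61 and 114 for SANT-2 against GANT-61; with the replicate number as a block, 259, 142, 204, 644 and 120; with quantile scaling and slide as a block, 281, 114, 187, 624 and 126. Slide as a block lowers the median SE from 0.201 to 0.132 or less. Whether the replicate number pairs ethanol with GANT-61 could not be told, so 142 is given as a value alone. Array weights gave 201 for cyclopamine, 3 for SANT-2, 1347 for GANT-61, 441 for cyclopamine against GANT-61 and 56 for SANT-2 against GANT-61. A fit of the compared groups alone gave 53 for cyclopamine, 5 for GANT-61, 35 for cyclopamine against SANT-2 and 120 against GANT-61, with fewer arrays. A minimum change of 2-fold left 48, 45 and 83 for cyclopamine against ethanol, SANT-2 and GANT-61, and an adjusted p under 0.01 left 65 for cyclopamine, 11 for GANT-61 and 112 between them. Without slide 2, GANT-61 gave 101 and cyclopamine against GANT-61 gave 318. For GANT-61, 11 genes passed without ethanol 2 and 31 without ethanol 4, the range over single arrays. The overlap of cyclopamine and GANT-61 was 11 with slide as a block and 6 with the replicate number as a block. The hedgehog-responsive differences of cyclopamine from ethanol, SANT-2 and GANT-61 were -1.26, -1.31 and -1.33 with arrangements within slides or within replicate numbers as a block, and -1.34, -1.39 and -1.43 without slide 2; they lost the call because too few arrangements remain. Of the lists, 5 shifted under cyclopamine, 2 with an estimated correlation, and 3 to 7 over single arrays left out, 3 without cyclopamine 5 and 7 without ethanol 5. Under SANT-2 the 0 became 1 with median centring, the background correction, slide as a block, the replicate number as a block, the compared groups alone or quantile scaling with slide as a block, and 3 with no filter or without slide 2; single arrays left out gave 0 to 3, with 1 without ethanol 1, ethanol 5 or SANT-2 3, 2 without SANT-2 1 and 3 without SANT-2 2. Under GANT-61 the 2 became 1 with quantile scaling, the authors' table, the background correction, a filter on all 20 arrays, an adjusted p under 0.01 or without slide 2, 0 with array weights or an estimated correlation and 4 with the replicate number as a block; single arrays left out gave 1 to 6, with 1 without ethanol 3 or ethanol 4 and 6 without ethanol 5. Where no reason is given, the cause was not tested. Signal over background limits the 3224 dim genes, which were not tested.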

Other observations

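The genes in the first paragraphs, and those of the list of motile cilia genes, were chosen after the results were seen; the tests of the cilia list were written down before its values were computed.

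Further genes also fell under cyclopamine. The troponin I gene tnni1c changed by -2.68 ± 0.23 (6.42-fold, adjusted p = 7.47e-07), the caveolar coat gene cavin4a by -2.38, smpx by -1.81, myoz2b, whose product sits at the Z-disc, by -1.41, the small heat shock protein gene hspb7 by -1.25, xirp1 by -0.80 and the myogenic cofactor gene vgll2b by -0.79. The gluconeogenesis gene fbp2 changed by -2.43 and the histamine-degrading enzyme gene hnmt by -2.34 (adjusted p = 5.22e-09). foxd5 fell by 2.36 on the log2 scale, the thyrotropin-releasing hormone gene trh by 2.17, sst6.1 by 1.58, six6b by 1.22, sim2 by 1.16, foxb1a by 1.02 and foxb1b by 0.78. The motor neuron gene mnx2a changed by -1.98, the growth factor gene fgf8b by -1.23, the vascular growth factor gene vegfaa by -1.14 (adjusted p = 0.000638) and the heparan sulfatase genes sulf2b and sulf2a by -1.21 and -0.88.

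Some genes passed with slide as a block only. Under cyclopamine these included emx3 (0.42), eomesa (0.86) and bhlhe22 (0.50), which were higher, and actn2b (-1.58), myh7 (-0.77) and shox2 (-0.77), which were lower. Under GANT-61, the higher ones included sycp3 at 1.92 (adjusted p = 0.0297), figla at 1.17 (adjusted p = 0.0338), spdya at 0.99 (adjusted p = 0.00446), gdf3 at 0.82 (adjusted p = 0.0424), crygn1 at 1.46 (adjusted p = 0.00146), crygs4 at 0.84 and grifin at 1.18, and the lower ones f9b at -0.84 and serpind1 at -0.63. These are single genes, and no list made of them was tested. crygn1 is a member of the lens crystallin list, which did not pass the list test under GANT-61.

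Genes of motile cilia were among those lowered by cyclopamine, with the dynein regulator drc3 at -0.67, daw1 at -0.74, the central pair gene spag6 at -0.52, cfap52 at -0.79 and dnaaf6 at -0.54. The hypothesis that motile cilia genes fall as a group was tested on 81 other cilia genes. Of these 32 were measured and 0 called without a block, though some passed with slide as a block. Their mean changed by -0.36, with 27 of 32 lower and 5 of 5 cyclopamine arrays under the ethanol mean (exact permutation p = 0.00794, the smallest possible), and with slide in the model the interval was -0.49 to -0.23. zmynd10 differed by -0.80, drc2 by -0.87 and the regulator foxj1b by -0.60, and each passed with slide as a block (adjusted p = 0.00446, 0.00874 and 0.0214). cfap20 differed by 0.04 and lrrc23 by 0.20, and neither passed in either fit. The mean differed by 0.01 under SANT-2 (exact permutation p = 0.952) and by 0.08 under GANT-61 (exact permutation p = 0.254), which is consistent with a fall of the group under cyclopamine, a hypothesis found and tested on the same arrays.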
